A study of Mus musculus with 6 samples.

How the data were processed

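RNA-seq was measured in 2 Acta2 KO and 2 WT samples and ATAC-seq in 1 KO and 1 WT sample of mouse cardiac fibroblasts, grouped by the genotype in their labels. Per the labels' protocols, libraries were sequenced as 150 bp paired reads, RNA libraries with a low-input kit that is not stated to keep strand, and ATAC-seq libraries from 10000 cells each.

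The authors deposited 1 table of estimated counts per gene for the 4 RNA-seq samples. Per the labels' protocols, reads were trimmed with Trim Galore 0.6, assessed with FastQC and aligned to mm10 with STAR 2.5.3a at default settings. The protocols also speak of values adjusted to TPM, but the deposited values sum to between 8429166 and 11370115 per sample and 10.8 to 12.2% of them are not whole, so they were treated as estimated counts. The counting program and annotation are not given in the sources used here. Estimated counts divide reads among genes by a model, so a gene that shares sequence with another is uncertain, and without strand an antisense partner cannot be separated. Whole counts had been assumed when the tests were planned. The estimates were rounded to whole numbers, and the planned test was kept.

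For ATAC-seq, the deposited files are peak lists. Per the labels' protocols, reads were trimmed with Trim Galore 0.6 and aligned to mm10 with Bowtie2 2.3, only unique alignments were kept, duplicates and mitochondrial alignments were removed, and MACS2 called peaks in each sample separately against a genome-wide background. Its version and its q-value threshold are not given in the sources used here, and the smallest deposited −log10 q-value was 1.86 in KO and 1.70 in WT. The deposited columns hold an integer score, the fold enrichment (a ratio to the library's background) and the −log10 p-value and −log10 q-value at the summit, per the labels' naming of MACS2 and its column order. Each fold in a list was a whole multiple, within 0.05 of a step, of 0.425 in KO and 0.4108 in WT. If the caller adds 1 to pileup and background, these steps stand for backgrounds of 1.35 and 1.43 fragments, which would put the depths of the libraries close to each other. No other depth is given for these libraries, and whether cut sites were shifted is not stated.

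Gene coordinates were compared with GENCODE M21 for GRCm38, the assembly also called mm10. Of 25746 genes in the table, 25635 were found by identifier and 25471 had identical coordinates, and no peak ended beyond a chromosome of that assembly. Start sites are the 5' ends of GENCODE genes, and coordinates are 1-based.

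Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr (minimum count 10), TMM factors, a quasi-likelihood fit of genotype without further terms, and Benjamini-Hochberg adjustment over 12192 genes at 0.05. The SE is the absolute log2 fold change divided by the square root of F. CPM uses TMM-scaled library sizes. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 25 lists with at least 3 tested members, leaving out the sex-linked list, as fixed in advance. They were repeated with an estimated correlation, which kept 0 of 11 calls in a fit with 2 residual degrees of freedom, and with fry, whose directional test called 16 lists and whose mixed test called 24. The directional test of fry asks only whether members move one way on balance and does not compare a list with other genes.

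The 27 lists were fixed before the data were examined: the actins, contractile genes, focal adhesion genes, matrix, TGF-β response, SRF and MRTF targets, YAP and TAZ targets, fibroblast identity, cell cycle, interferon, inflammatory cytokines, sterol synthesis, p53 targets, unfolded protein response, heat shock, glycolysis and hypoxia, osteochondrogenic and lipid genes, markers of 8 other cell types, and sex-linked genes. Named genes were also fixed by rule: Acta2, the other actins, 11 genes of the contractile and matrix programme, the 10 highest and 10 lowest log2 fold changes among called genes with a mean log2 CPM of at least 2 and non-overlapping genotypes, and up to 4 called members per list with the smallest p (up to 2 by level where none was called). Members behind a count of 5 or fewer are named as well, without being recomputed one by one under the alternatives.

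Replicates were compared before use. Within a genotype the chi-square per degree of freedom over genes was 1.62 in KO and 1.53 in WT, above sampling noise, and 13.7 to 14.7 between genotypes, so all 4 samples were kept. The test was checked on simulated counts for the real genes. At the fitted BCV of 0.0311 it recovered 36% of genes changed 1.2-fold, 58% at 1.5-fold, 84% at 2-fold and 96% at 4-fold, with 2 false calls among 12022 genes. At a BCV of 0.2 it recovered 0% at 1.2-fold and 1.5-fold, 24% at 2-fold and 96% at 4-fold among 12038 genes. Each run changed 50 genes per fold, far fewer than the 4352 called in the data. The adjustment was therefore stricter there, and these shares need not carry over. Shared sequence is the share of 100-base windows of a gene's GENCODE transcripts found in another gene's transcripts, on 1 in 8 windows.

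Peak lists were compared with bedtools 2.31.1, and shares have 95% Wilson intervals. For each gene the peak with the highest fold among those overlapping the 1 kb to each side of the start was taken. Its fold at the summit, which may lie outside that window, was expressed as a percentile in its own list, with 0 where there was no peak. List medians of the KO minus WT difference were set against 10000 random lists from 20 bins of mean expression. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9. Alternatives were other scalings, filters and tests (DESeq2 1.42.0, limma-voom, the edgeR exact test), a replicate block, each library left out in turn, sex-linked and mitochondrial genes left out, stricter thresholds and other overlap rules. An assumed BCV of 0.1 and 0.2 and a test against 1.5-fold were added after seeing the data. Xist and Tsix were not analysed here, and 1 gene of the fixed rule is not reported here.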

Results

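Gene expression and chromatin accessibility were measured in mouse cardiac fibroblasts, the connective tissue cells of the heart that turn into contractile, matrix-producing myofibroblasts after injury or under TGF-β. The labels compare cells in which Acta2, the gene of α-smooth muscle actin, was knocked out (KO) with wild-type (WT) cells. RNA-seq was done on 2 KO and 2 WT samples, and ATAC-seq, which maps open chromatin by transposase insertion, on 1 KO and 1 WT sample. The labels describe fibroblasts of WT and floxed Acta2 mice that received Cre from an adenovirus and then TGF-β for 2 days, but also fibroblasts sorted by a Tcf21 lineage reporter after infarction in vivo, and do not say which of these each library was made from. The labels of all samples also name tamoxifen, at 75 mg per kg per day for 5 days from 6 weeks of age, and infarction at 9 weeks of age. The RNA-seq libraries held 11370115 and 10864365 estimated counts in KO and 8429166 and 9096811 in WT. Nothing in the labels says that the replicates came from separate cultures or animals, so the p-values below measure only the spread between these samples, which may be technical. The study's question was what losing this actin does to the expression programme and the open chromatin of the fibroblasts.

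Acta2, the targeted gene, was lower in both KO libraries. It had 2921.15 and 2909.21 estimated counts in KO and 18230 and 19889.62 in WT. The level was 261 ± 6.74 library-size normalised counts (CPM) in KO and 2193 ± 9.72 CPM in WT (SD, n = 2), a log2 fold change of -3.07 (SE 0.030, adjusted p = 1.59e-32, edgeR quasi-likelihood test). In KO, 11.9% of the WT level remained. The gene (ENSMUSG00000035783) lies on the minus strand of chromosome 19 at 34241090 to 34255590 in mm10. The labels do not state which exons were removed, so the counts do not tell full-length transcripts from transcripts that lack the deleted part.

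Transcripts of the other actin genes were more abundant in KO. Of the 5 listed isoforms, 4 were tested and all 4 rose, also when adjusted over the list alone. Actg2, the enteric smooth muscle γ-actin, rose from 16.2 ± 0.766 to 67.0 ± 1.93 CPM (SD, n = 2), a log2 fold change of 2.04 (SE 0.091, adjusted p = 1.94e-16 by edgeR). Acta1, the skeletal muscle α-actin, rose from 90.8 ± 4.58 to 235.0 ± 0.325 CPM, a log2 fold change of 1.37 (SE 0.051). The cytoplasmic actins Actb and Actg1 started far higher, at 6433 and 1188 CPM in WT, and rose by a log2 fold change of 0.26 and 0.39. Actc1, the cardiac α-actin, was not tested, with estimated counts of 8 and 3 in KO and 0 and 1 in WT. As a list the other actins were higher than the remaining genes (camera, adjusted p = 0.00107), but the adjusted p was 0.211 with an estimated correlation. The calls of Actb and Actg1 ended when a biological coefficient of variation (BCV) of 0.1 or 0.2 was assumed in place of the fitted one, which left 2 of the 4. Actg1 shares 29.9% of its 100-base windows with other genes, so that its value is uncertain. In the same libraries macrophage and endothelial markers had median log2 fold changes of 0.844 and 0.518, and pericyte and smooth muscle markers a median of 0.369. Myh11 and Lmod1, smooth muscle genes that are also on the contractile list, rose by 2.99 and 2.04. Without them the median was -0.58, which says little about smooth muscle cells.

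**Figure D1:**
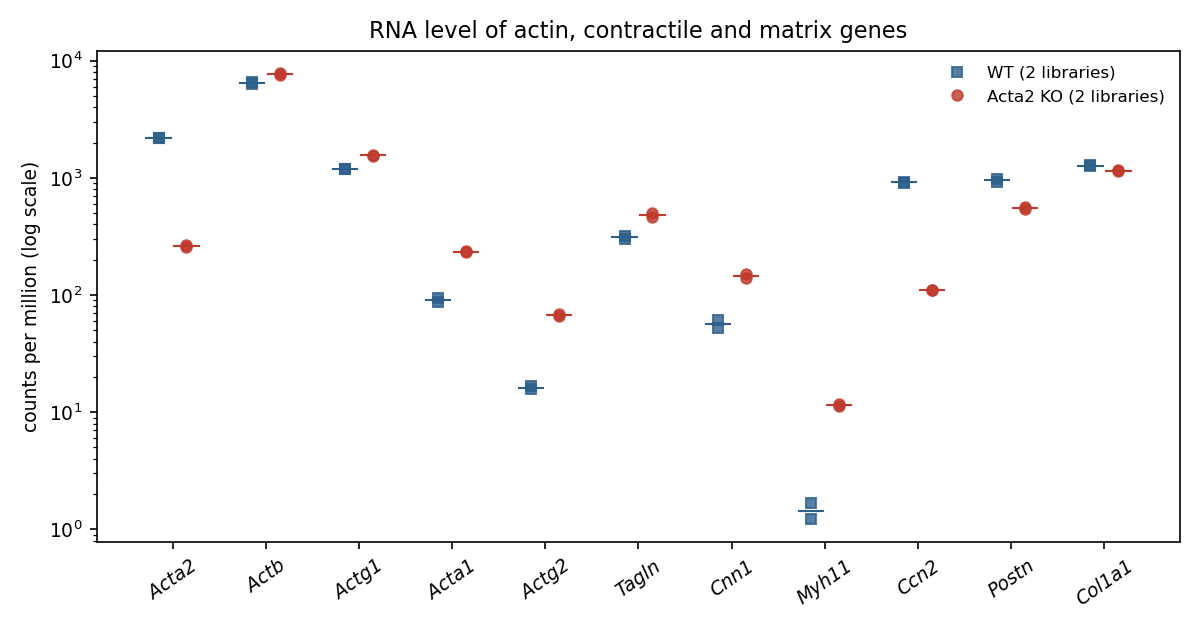
Library-size normalised counts (CPM, y axis, log scale) of 11 genes (x axis) in each of the 2 WT libraries (blue squares) and 2 Acta2 KO libraries (red circles), with a short line at each group's mean. Acta2 and Ccn2 were lower in KO, with log2 fold changes of -3.07 each, while Actg2, Acta1, Cnn1 and Myh11 were higher in both KO libraries than in both WT libraries.

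Beyond Acta2, the KO and WT libraries differed in many genes, mostly by small amounts. Of 12192 tested genes, 4352 changed, 2231 upward and 2121 downward, and their median absolute log2 fold change was 0.404. A change of at least 2-fold was seen for 610 genes, 364 higher and 246 lower, while 3015 of the changed genes moved by less than 1.5-fold. The 10 largest rises among called genes with a mean log2 CPM of at least 2 and non-overlapping genotypes were led by Cda, the cytidine deaminase of nucleotide salvage, at 15.2 ± 2.60 CPM in KO against 0.452 ± 0.30 CPM in WT (SD, n = 2; log2 fold change 5.01, SE 0.31). Map3k1, a kinase upstream of JNK, Myh11, the smooth muscle myosin heavy chain, and Ang2, a ribonuclease of the angiogenin family, followed with log2 fold changes of 3.10, 2.99 and 2.98. The WT estimated counts were low for Cda (2 and 6), Map3k1 (7 and 7), Myh11 (14 and 11) and Ang2 (11.3 and 10), so the size of these rises is uncertain. Hddc3, the vesicle protein gene Syt13, the transcription factor Sox11 and the acyltransferase Mboat2 rose by 2.71, 2.33, 2.28 and 2.25. The values of Rpl29 (2.86) and Fam220a (2.63) are uncertain, since 24.2% and 95.5% of their 100-base windows also occur in other genes.

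On the lower side, Ccn2, a matricellular protein induced by TGF-β and by YAP, fell from 919 ± 10.3 to 109 ± 0.236 CPM (SD, n = 2), a log2 fold change of -3.07 (SE 0.038, adjusted p = 5.96e-30 by edgeR) and as far as Acta2 itself. Ucp2, a mitochondrial carrier, fell from 106 ± 3.30 to 5.61 ± 1.48 CPM, and Il1rl1, the receptor of interleukin-33, from 63.6 ± 4.99 to 3.76 ± 0.108 CPM, with log2 fold changes of -4.23 and -4.08. Cramp1l, the ephrin receptor Epha3 and the collagen gene Col28a1 fell by 3.06, 2.68 and 2.64 on the log2 scale. The remaining 3 of the 10 largest falls, Tagap (-5.53), Hmga1b (-5.09) and Hist1h2bq (-2.52), share 34.3%, 81.05% and 96.1% of their windows with other genes and are uncertain. DESeq2 called 2058 genes. In edgeR the count moved with the spread assumed, to 1780 genes with a BCV of 0.1 and 398 with 0.2, against a fitted common BCV of 0.0311. Of the 113 named genes other than Acta2, all called, 104 kept the call with DESeq2 and 44 with an assumed BCV of 0.2.

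Genes of the contractile apparatus were higher in KO. Of 23 tested smooth muscle contractile and stress fibre genes, 16 rose, 1 fell and 6 did not pass (18 and 1 adjusted over the list alone), with a median log2 fold change of 0.388. The 1 that fell was Myh10, a non-muscle myosin, at -0.26. Cnn1, the calponin that binds actin filaments, rose from 56.9 ± 6.51 to 146 ± 7.56 CPM (SD, n = 2; log2 fold change 1.36, SE 0.065). Lmod1, which nucleates actin filaments in smooth muscle, rose by a log2 fold change of 2.04, and the filament-associated Csrp1, the myosin light chain Myl9 and Tagln by 0.93, 0.85 and 0.61. Focal adhesion and integrin genes moved the same way, with 14 of 19 rising and 2 falling (15 and 2 adjusted over the list alone): Itga5, the fibronectin receptor subunit, rose by 1.40, Pdlim5 by 0.41, Ilk by 0.30 and Zyx by 0.27, and the integrin genes Itgav and Itgb5 fell by 0.20 and 0.21. Among 23 tested targets of SRF and its actin-sensing partners MRTF, 15 rose and none of the rest passed (16 and 0 adjusted over the list alone), Fhl1 by 1.2 on the log2 scale. Camera called the lists higher at adjusted p = 9.11e-06, 0.00127 and 1.48e-05 in this order, and the adjusted p was 0.211 for each with an estimated correlation. Contractile and SRF lists share members, and without genes of other lists the contractile call was lost. With an assumed BCV of 0.2 the calls of Tagln, Myl9, Pdlim5, Ilk and Zyx ended. Macrophage and endothelial markers were also higher in these KO libraries, with median log2 fold changes of 0.844 and 0.518.

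Matrix genes were lower in KO. Of 30 tested collagen and myofibroblast matrix genes, 18 fell, 2 rose and 10 did not pass (21 and 3 adjusted over the list alone), with a median log2 fold change of -0.270. Postn, the periostin gene of activated fibroblasts, fell from 952 ± 28.4 to 549 ± 16.6 CPM (SD, n = 2; log2 fold change -0.79, SE 0.033). Col11a1 fell by 0.99, the proteoglycan Dcn by 0.83, Col3a1 by 0.52, Col1a2 by 0.46, the fibronectin gene Fn1 by 0.28 and Col1a1 by 0.15 on the log2 scale, while Col4a1 and Tnc rose by 0.32 and 0.38. Camera gave an adjusted p of 0.000121 for the list, and the adjusted p was 0.371 with an estimated correlation. Of the 7 genes named as lower, Col11a1 kept its call with an assumed BCV of 0.2 and the others did not. The macrophage and endothelial marker medians of 0.844 and 0.518 belong to the same comparison.

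TGF-β response genes were not called as a list by camera (adjusted p = 0.0947) but were lower by directional fry (adjusted p = 0.013): of 19 tested, 3 rose and 7 fell (3 and 7 adjusted over the list alone), with a median log2 fold change of -0.061. Ccn2 stood far from the others, while Cdkn2b fell by 0.98, Bhlhe40 by 0.43 and Ltbp2 by 0.39 on the log2 scale. Tgif1 and Meox1 rose, by 0.18 and 0.64. Among 22 targets of YAP and TAZ, 10 rose and 4 fell (the same numbers adjusted over the list alone), with a median of 0.157 and no list call (adjusted p = 0.190): Tgfb2, F3 and Axl rose by 0.89, 0.65 and 0.31, and Ccn2, Myof, Nt5e and Rbms3 fell, the last 3 by 0.34, 0.72 and 0.25. Cardiac fibroblast identity genes went both ways, with 5 of 20 rising and 6 falling (7 and 6 adjusted over the list alone, camera adjusted p = 0.830, directional fry lower at adjusted p = 0.0356). Mfap4 fell by 1.54, the fibroblast transcription factor Tcf21 by 0.82, Dpt by 0.54, Dpep1 by 0.53 and the PDGF receptor gene Pdgfra by 0.19 on the log2 scale, while the cardiac transcription factors Gata4 and Hand2 rose by 0.96 and 0.45 and Gsn, Cd34 and Thy1 by 0.11, 0.33 and 0.30. The call of Pdgfra was lost with DESeq2, with library size as the only scaling and without any 1 of the 4 libraries. With an assumed BCV of 0.2, Bhlhe40, Ltbp2, Tgfb2, F3, Axl, Tcf21, Dpt, Dpep1, Pdgfra and Gata4 lost their calls. In this comparison too, the macrophage and endothelial marker medians were 0.844 and 0.518.

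Sterol synthesis genes were lower in KO, with the smallest p of all lists by camera at the preset correlation, though not by fry or with an estimated correlation. None of its 21 tested genes rose and 19 fell, also adjusted over the list alone, with a median log2 fold change of -0.532 (camera, adjusted p = 1.91e-10, and adjusted p = 0.211 with an estimated correlation). Fdft1, the squalene synthase, fell from 160 ± 0.779 to 80.02 ± 2.95 CPM (SD, n = 2), a log2 fold change of -1.0 (SE 0.052), and Hmgcs1, Idi1 and Fdps fell by 0.91, 0.90 and 0.83. Parts of Idi1 and Fdps, 16.3% and 21.4% of their windows, also occur in other genes, and with an assumed BCV of 0.2 only Fdft1 of these 4 kept its call. Interferon response genes were lower too: 19 of 26 fell and 3 rose, also adjusted over the list alone, with a median of -0.344 (camera, adjusted p = 3.31e-05, and adjusted p = 0.211 with an estimated correlation). Ifit3, Ifit3b and Ifit1, antiviral effector genes, fell by 1.35, 1.34 and 1.09, and Zbp1 by 0.61 on the log2 scale, while Stat2, Rsad2 and Ccl5 rose by 0.29, 0.54 and 0.43. Ifit3 and Ifit3b share 29.7% and 24.4% of their windows with other genes, and Zbp1 lost its call with an assumed BCV of 0.2. Together with Ifit2, these Ifit genes lie within 1 Mb of Acta2, and among the 22 members elsewhere 15 fell and 3 rose, with a median of -0.264. Of the 14 other tested genes within 1 Mb of Acta2, 8 changed, against 35.7% of all tested genes. Whether their position bears on the falls of the Ifit genes was not tested. Beside the sterol and interferon genes, macrophage and endothelial markers moved upward in these libraries, with medians of 0.844 and 0.518.

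Cell cycle genes fell in 9 of 25 cases and rose in 2, also adjusted over the list alone (median -0.221, camera adjusted p = 0.0386, and adjusted p = 0.437 with an estimated correlation). Bub1, Ccnd1 and Ccnb1 fell by 1.47, 0.67 and 0.61 on the log2 scale and Rrm2 and Mcm3 rose by 0.25 and 0.24. This list call was lost with DESeq2, with the edgeR exact test and without WT replicate 2, and Ccnd1, Ccnb1 and Rrm2 lost their calls with an assumed BCV of 0.2. Ccnb1 shares 16.9% of its windows with other genes. Of 18 tested p53 target genes 14 rose and 1 fell (17 and 1 adjusted over the list alone), with a median of 0.256 (camera, adjusted p = 0.00107, and adjusted p = 0.211 with an estimated correlation). Trp53inp1, Aen, Eda2r and Pmaip1, genes of apoptosis and stress signalling, rose by 0.38, 0.38, 0.36 and 0.34, and the death receptor gene Tnfrsf10b fell by 0.28. The 4 that rose lost their calls with either assumed BCV, as the list did with a BCV of 0.2. The macrophage and endothelial marker medians beside these cell cycle and p53 values were 0.844 and 0.518.

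Macrophage and endothelial markers were higher in KO, and camera called no other marker list. Macrophage and leukocyte markers rose in 8 of 12 cases and fell in none, also adjusted over the list alone, with a median log2 fold change of 0.844 (camera, adjusted p = 7.2e-05, and adjusted p = 0.211 with an estimated correlation). Some listed markers were near the floor in every library. Ptprc had 11 and 9 estimated counts in KO and 5 and 1 in WT, Mrc1 0 and 5 in KO and 5 and 0 in WT, and Fcgr1 0 in each. Lyz2, the macrophage lysozyme and the most abundant of these 4 macrophage markers, rose from 50.8 ± 2.82 to 95.5 ± 2.49 CPM (SD, n = 2), and Adgre1, Cd14 and Cd68 rose by 1.58, 0.78 and 0.71 on the log2 scale. Csf1r differed less than Lyz2, with 114.96 and 114.76 estimated counts in KO and 71.41 and 81.27 in WT, whose library totals were smaller. The list median therefore does not hold for each marker. Endothelial markers rose in 9 of 12 cases and fell in 1 (10 and 1 adjusted over the list alone), with a median of 0.518 (camera, adjusted p = 0.00127, and adjusted p = 0.271 with an estimated correlation): Tie1, Emcn and Egfl7 rose by 2.09, 1.5 and 0.52, and Flt1 fell by 0.64. Epicardial and mesothelial markers fell in 4 of 8 cases and rose in 1, also adjusted over the list alone (camera adjusted p = 0.210, directional fry lower at adjusted p = 0.0301). Upk3b, Wt1, Msln and Upk1b fell by 0.85, 0.74, 0.52 and 0.20 and Krt19 rose by 0.49; the call of Upk1b was lost with DESeq2 and without KO replicate 2, and that of Msln without KO replicate 1. Pericyte and smooth muscle markers rose in 3 of 7 cases and fell in 3, also adjusted over the list alone (camera adjusted p = 0.701, directional fry higher at adjusted p = 0.0256). Mcam rose by 1.1 and Steap4, Rgs5 and Cspg4 fell by 1.15, 0.60 and 0.58, and the other 2 that rose, Myh11 and Lmod1, are also on the contractile list. Without Myh11 and Lmod1, which are smooth muscle genes, the median of this list turned to -0.58 and says little about smooth muscle cells. Summed over each list, macrophage markers made up 193 and 195 CPM in KO and 111 and 107 CPM in WT, and endothelial markers 223 and 239 CPM in KO and 176 and 175 CPM in WT. With an assumed BCV of 0.2, Lyz2, Cd14, Cd68, Egfl7, Flt1, Upk3b, Upk1b, Msln and Krt19 lost their calls.

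**Figure D2:**
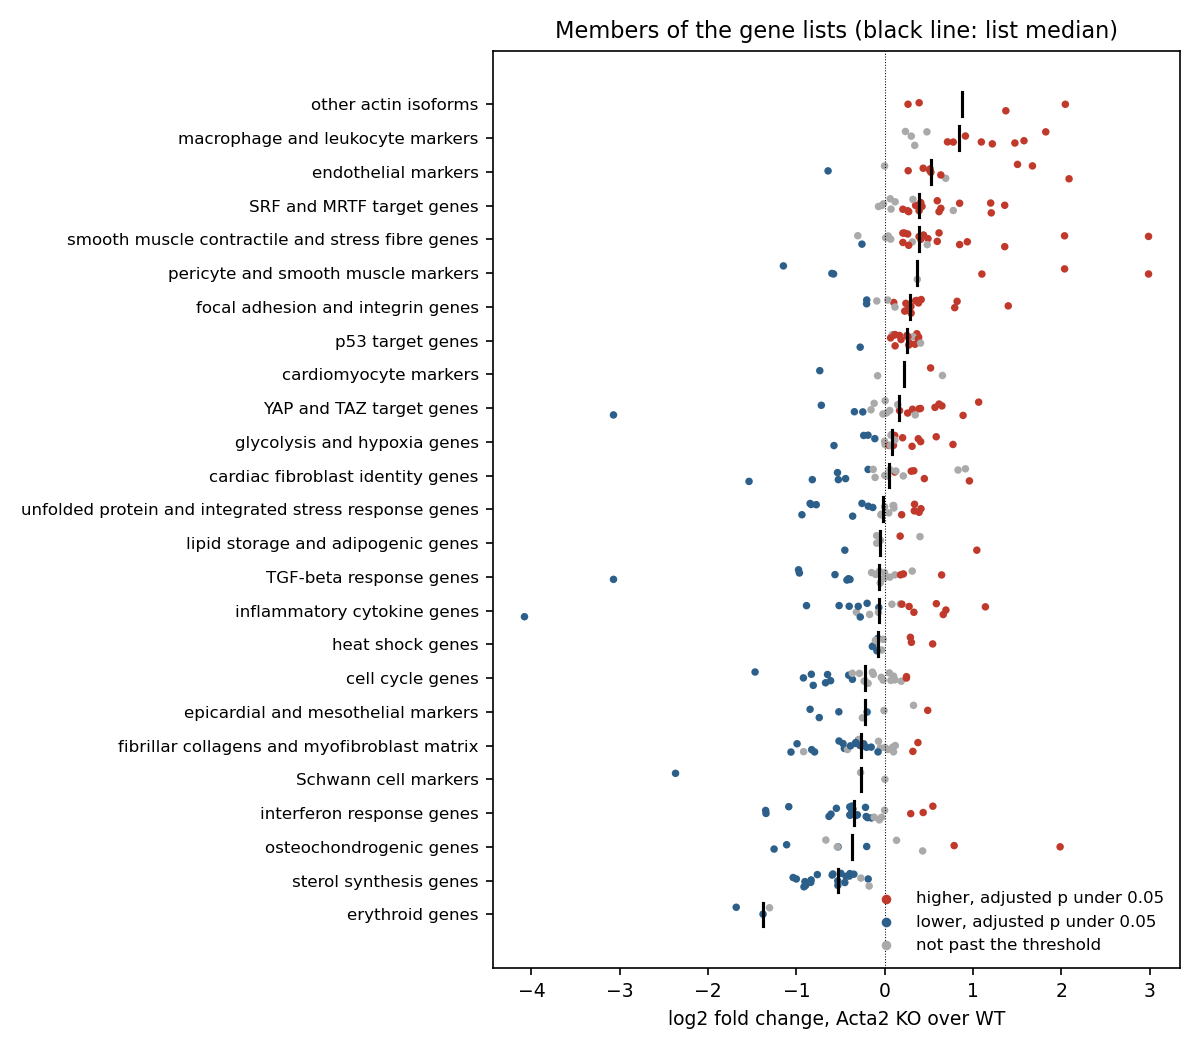
Log2 fold change of KO over WT (x axis) for the tested members of each gene list (rows, ordered by their median, black line). Red and blue points passed an adjusted p of 0.05 upward and downward by edgeR, and grey points did not. None of the 21 sterol synthesis genes rose, and the 4 other actin genes were all higher.

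The ATAC-seq libraries had nearly the same number of peaks. The authors' peak lists held 121748 peaks in KO and 123935 in WT, which covered 126.6 and 126.4 Mb with median widths of 752 and 736 bp. With 1 library per genotype these values have no replicate check. Of the KO peaks 76.3% (95% Wilson interval 76.0 to 76.5%) overlapped a WT peak by at least 1 base, and of the WT peaks 75.6% (75.4 to 75.9%) overlapped a KO peak. The intervals cover counting error only. Peaks found in 1 list only were weak, with a median fold enrichment of 4.25 in KO and 3.70 in WT against 7.65 and 6.98 for shared peaks. Of the 20000 KO peaks with the smallest p, 99.94% overlapped some WT peak, as did 99.94% in the reverse direction. Promoters, taken as 1 kb to each side of a protein-coding start, held 13.2% of the shared peaks of either list, but 2.03% of the unshared KO peaks and 1.63% of the unshared WT peaks. The share of overlapping peaks moved with the rule, to 60.9% and 59.8% where at least 0.5 of both peaks had to overlap, and a fold enrichment of at least 5 left 80606 KO and 70006 WT peaks.

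Chromatin over Acta2 was open in both libraries. A peak over its transcription start spanned 34253604 to 34256556 of chromosome 19 in KO, with a summit in the first exon and a fold enrichment of 20.4, and 34251517 to 34256463 in WT, with a fold of 18.1. These peaks stood at the 92.5 and 92.6 percentile of their own lists by fold. Within the gene and 2 kb to each side, the KO list had 7 peaks and the WT list 6. The long WT peak at the 5' end corresponded to 2 separate KO peaks, the second at 34251506 to 34252776 with a fold of 8.08.

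**Figure D3:**
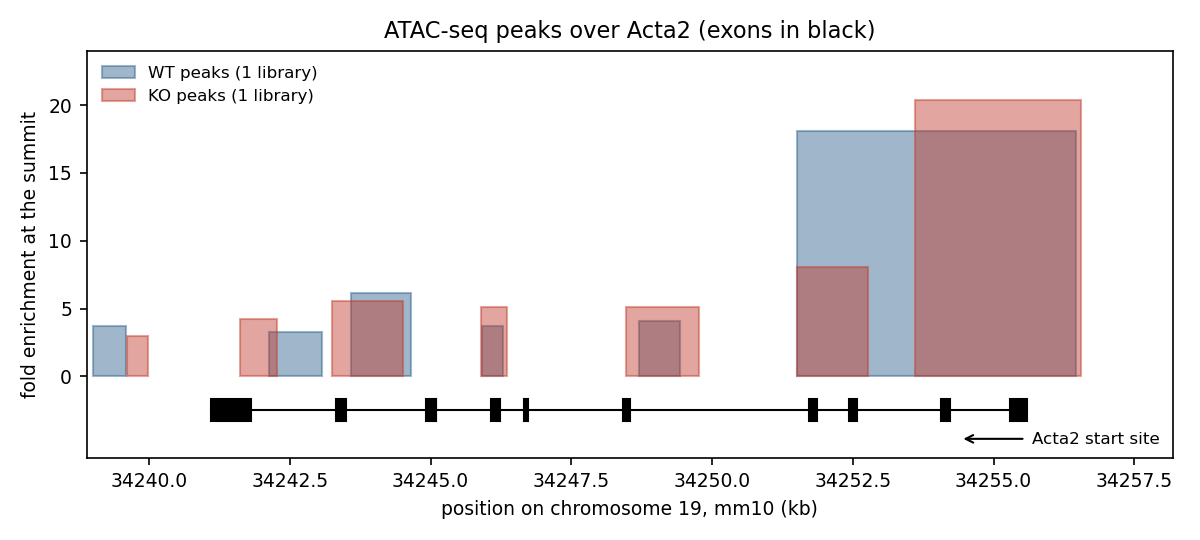
Peaks of the WT (blue) and KO (red) ATAC-seq libraries along Acta2 on chromosome 19 (x axis, kb in mm10), drawn from start to end at the height of the authors' fold enrichment at the summit (y axis). Exons are black, and the arrow shows the direction of transcription from the start site. The peaks over the start site reached a fold of 20.4 in KO and 18.1 in WT.

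Of the 20 named genes with the highest and lowest RNA fold changes, 16 had a promoter peak in both lists and 4 (Tagap, Il1rl1, Col28a1 and Hist1h2bq) in neither. Each fold is the authors' value, and ranks within lists of different length describe each list and show no change between genotypes. At Ccn2 the promoter peak stood at the 99.9 percentile of the KO list and the 99.7 percentile of the WT list. At Ucp2 it stood at the 66.1 percentile in KO and the 94.9 percentile in WT, at Cda at 90.7 and 67.6, and at Postn at 42.6 and 90.2. A peak counted if any part of it lay within 1 kb of the start, so its summit could lie farther away. At Postn the WT peak spanned 54357461 to 54361337 and the KO peak 54360656 to 54361282, so they may mark different sites. Lyz2 and Acta1, picked by their gaps and higher in KO by RNA, stood at 71.8 each in KO and at 33.2 and 15.3 in WT. The Acta1 peaks, 123891547 to 123894341 in KO and 123894784 to 123895517 in WT, do not overlap and mark different sites. Other gaps ran against the RNA. Msln, whose RNA was lower in KO, stood at 81.9 in KO and 33.2 in WT. Its KO peak spanned 25751289 to 25754699 and its WT peak 25753733 to 25754905, so these too may mark different sites. Egfl7 and Eda2r, whose RNA was higher in KO, stood at 5.70 and 68.2 in KO and at 24.7 and 84.8 in WT. Neither list had a peak within 1 kb of the start of Actg2. Across the 11312 tested genes with a promoter peak in both lists, the log2 fold change of RNA and the KO minus WT difference in percentile had a Spearman rho of 0.0515. Of the 364 genes at least 2-fold higher in KO, 183 stood higher by percentile in KO and 125 lower. Of 245 at least 2-fold lower, 78 stood higher and 124 lower, and of 7837 unchanged genes 3726 and 3691. These are relations across genes, which are not independent replicates. Of 25 lists, 3 had a median difference outside the middle 95% of 10000 random lists matched on expression: osteochondrogenic genes (median difference -7.63, below all random lists), epicardial and mesothelial markers (-2.68, percentile 2.47) and cardiac fibroblast identity genes (1.5, percentile 98.9). With 5 kb to each side the osteochondrogenic list remained outside, the identity list did not (0.44, percentile 79.0), and the epicardial and mesothelial median turned to 2.06 (percentile 96.2), inside the range. Random lists were not matched on promoter peak rank, so a list of middle-ranked promoters can fall outside for that reason. Cnn1, Col3a1 and Fhl1, with folds of 8.50 in KO and 8.22 in WT, stood at the 66.1 and 69.9 percentile. No adjustment was made over the 25 lists, and these positions do not show a change between genotypes. The contractile, focal adhesion, SRF and matrix lists lay between the 21.8 and the 70.8 percentile.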

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

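The assumed BCVs and the test against 1.5-fold were chosen after seeing the data. Counts of changed genes kept within 1.5 times of 4352 under every scaling, filter, limma-voom, the exact test and each left-out library (3392 to 3674; the lone sample left is then assumed to vary like the other group). They moved with DESeq2 (2058, all among the 4352, with 962 higher and 1096 lower), a fold of at least 2 (610, 364 and 246), an assumed BCV of 0.1 (1780, 1027 and 753) or 0.2 (398, 223 and 175) and the test against 1.5-fold (351, 186 and 165). The last 4 ask for larger changes by construction. For DESeq2 the cause was not tested. Changed actins other than Acta2 fell from 4 to 2 with either BCV and against 1.5-fold. Called lists fell from 11 to 0 with an estimated correlation, where the fit has 2 residual degrees of freedom. The log2 fold change of Acta2 stayed between -3.10 and -3.05. The replicate numbers showed no shared shift, which does not tell whether the samples were paired. Replicate differences correlated between genotypes at r = 4e-04 across all tested genes and at 0.036 across the 10094 with a mean log2 CPM of at least 2. A replicate block gave 4408 changed genes and the same 11 list calls, and of the named genes Hba-a1 and Hba-a2 lost their calls. Of the 113 other named genes, 26 lost their calls with a BCV of 0.1, 69 with 0.2, 58 against 1.5-fold and 9 with DESeq2. With each library left out in turn, Hba-a1 ranged from -2.30 to 1.33, Hba-a2 from -2.87 to 1.43, the erythroid median from -2.3 to 1.426 and the unfolded protein median from -0.02 to 0.004, each positive without WT replicate 1. The pericyte median turned to -0.58 without genes of other lists. These 3 list medians changed sign. Reading list reversals by the sign of the median was chosen after seeing the data; by the direction of the list test, as first read, 18 combinations of 6 lists and a setting reversed, 9 of them for heat shock genes, and none was called on either side. For ATAC-seq, a −log10 q of at least 5 left 78016 WT peaks (KO 89629), a fold of at least 5 left 80606 KO and 70006 WT peaks. Shared percentages were 60.85 of KO and 59.78 of WT with at least 0.5 of both peaks overlapping, 75.69 and 86.88 at a −log10 q of at least 5, and 83.62 and 83.76 among 20000 top peaks each. Lists outside the random range fell from 3 to 1 with 5 kb around the start. The causes of these moves were not tested. Small changes were often missed in simulation: 36% of 1.2-fold changes were recovered. Depth was not varied there, and far fewer genes were changed than were called in the data, so that this share need not carry over.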

Other observations

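Other gene groups changed in both directions. Inflammatory cytokine genes rose in 7 of 20 cases and fell in 8, also adjusted over the list alone (camera adjusted p = 0.743): Ptgs2, the inducible cyclooxygenase, rose by a log2 fold change of 1.14 and the neutrophil chemokine Cxcl5 by 0.69, while Cxcl12 fell by 0.89. Unfolded protein and integrated stress response genes rose in 5 of 20 cases and fell in 8 (6 and 8 adjusted over the list alone, camera adjusted p = 0.534, directional fry lower at adjusted p = 0.0114), and the amino acid and one-carbon enzymes Asns, Mthfd2 and Phgdh fell by 0.85, 0.83 and 0.78 and the chaperone Hsp90b1 by 0.26, while Atf4, Ddit3, Atf3, Creld2 and Chac1 rose by 0.39, 0.34, 0.33, 0.19 and 0.41. Glycolysis and hypoxia genes rose in 9 of 19 cases and fell in 4 (11 and 4 adjusted over the list alone, camera adjusted p = 0.238), with the glucose transporter Slc2a1 up by 0.41 and Bnip3 by 0.31, and Ndrg1, Adm, Hk2 and Aldoa down at log2 fold changes of -0.58, -0.24, -0.19 and -0.11. Osteochondrogenic genes rose in 2 of 10 cases and fell in 4 (2 and 5 adjusted over the list alone, camera adjusted p = 0.499): Fmod fell by 1.25, Mgp, an inhibitor of calcification, by 1.11, Sox9 by 0.53 and Spp1 by 0.20, and Alpl and Bmp4 rose by 1.99 and 0.79. Heat shock genes rose in 3 of 11 cases and fell in 3 (3 and 4 adjusted over the list alone, camera adjusted p = 0.972), with Hspa1a, Bag3 and Hspb1 up by 0.54, 0.30 and 0.29 and Hspa8, Hspe1 and Hsp90aa1 down at -0.09, -0.14 and -0.08. Hspa1a, Hspb1, Hspa8 and Phgdh share 52.8%, 44.7%, 28.2% and 27.0% of their windows with other genes. Lipid genes rose in 2 of 7 cases and fell in 1, also adjusted over the list alone (camera adjusted p = 0.950), with Cebpa and Angptl4 up by 1.04 and 0.17 and Scd1 down at -0.45. The sign of median, mean and test differed for fibroblast identity genes (median 0.045, camera lower), heat shock genes (median -0.078, mean 0.041) and lipid genes (median -0.050, mean 0.133), and for osteochondrogenic genes fry pointed higher at a median of -0.367. The calls of Cebpa and Angptl4 were lost with DESeq2, Cebpa also without any 1 of the 4 libraries and Angptl4 without KO replicate 2. Of the genes in this paragraph that were recomputed under the alternatives, Ptgs2 and Mgp kept their calls with an assumed BCV of 0.2 and the others lost them.

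Smaller marker lists had few tested members. Of 4 cardiomyocyte markers, Nppb rose by a log2 fold change of 0.52 and Tnnt2 fell by 0.74 (camera adjusted p = 0.674), both lost with DESeq2. Nppb was also lost without any 1 of the 4 libraries, and Tnnt2 without KO replicate 2 or WT replicate 2. Of 3 Schwann cell markers Cdh19 fell, with 5 and 5 counts in KO against 22 and 19 in WT (camera adjusted p = 0.198). Of 3 erythroid genes, Hba-a1 and Hba-a2 fell (3 adjusted over the list alone, camera adjusted p = 0.759), but the level in WT came from 1 library: Hba-a1 had 127.25 counts in WT replicate 1 and 11.30 in WT replicate 2, and without the former its log2 fold change was 1.33. Hba-a1 and Hba-a2 share 61.6% and 75.7% of their windows with other genes. None of the lymphocyte markers was tested. Of 4 tested sex-linked genes, Ddx3y, Eif2s3y and Kdm5d were lower in KO, also adjusted over the list alone, at log2 fold changes of -0.51, -0.47 and -0.66, and Uty was at -0.01. The call of Kdm5d was lost with DESeq2 and without KO replicate 1, KO replicate 2 or WT replicate 2.

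Of the tests in this part, those of shared actin sequence, of the other genes and the shared sequence of the chromosome 4 window, and of the CArG boxes were laid out before their results were seen. The others, the choice of that window, and the reading of the tests of extra copies and of CArG boxes came after. Tests of 3 explanations for genome-wide clustering, also laid out in advance, were dropped once no clustering was found.

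Acta2 kept 11.9% of its WT level in the KO libraries. Reads of other genes that match Acta2 exactly over 150 bases are argued against, since 0% of the 150-base windows of its transcripts occur in a transcript of another gene. That measure misses reads with mismatches. The estimated counts of Acta2 in KO, 2921.15 and 2909.21, are not whole, so misassigned reads of other actin genes stay open. Cells that kept an intact allele, or a shortened transcript from the deleted allele, could each leave Acta2 reads in KO. These 2 cannot be told apart at 11.9% because the table has 1 value per gene and no reads per exon.

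Ccn2 fell as far as Acta2, at a log2 fold change of -3.07. A general fall of TGF-β response genes to that extent is argued against: the median of the other 18 tested genes was -0.056 (quartiles -0.407 and 0.1), and the lowest of them, Cdkn2b, reached -0.98. The other 21 targets of YAP and TAZ had a median of 0.167 (quartiles -0.021 and 0.404), with Nt5e lowest at -0.72. A closed promoter stays open: the KO list has a peak at the Ccn2 start, at the 99.93 percentile by fold, but 1 library excludes nothing. An effect of the genotype on Ccn2 by another route was not tested.

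Genes changed at least 2-fold were not clustered genome-wide: 348 of the 610 had another such gene within 1 Mb, and 1000 shuffles gave a median of 339, with 311 to 366 in the middle 95%. Of 524 windows of 5 Mb, 1 stood out (one-sided binomial test, adjusted p = 0.0016): at 135000001 to 140000000 of chromosome 4, 13 of 56 tested genes changed at least 2-fold and all 13 were higher in KO, against 5.0% of genes in the genome. These include Cda, the 3 complement genes C1qa, C1qb and C1qc, and, at the highest level, Capzb, a subunit of the actin capping protein, at 990.4 ± 23.9 CPM in KO and 385 ± 24.6 CPM in WT (SD, n = 2), all but Cda chosen after their values were seen. The binomial test treats genes as independent, though the 3 complement genes lie side by side, and it was not repeated without them. In WT, Cda, Alpl, Sh2d5, C1qa and C1qb of the 13 stood at 0.452, 0.692, 0.692, 0.752 and 0.876 CPM, so their folds are uncertain.

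Near-identical gene copies are argued against for this window, since 1 of the 13 genes (Aldh4a1) shares 10% or more of its sequence windows. A larger share of macrophages could account for the 3 of the 13 that are on that marker list (C1qa, C1qb and C1qc, at 2.10, 3.10 and 3.09 CPM in KO, against 95.5 CPM for Lyz2) and stays open for the others, since a short marker list does not show what macrophages express; the sorting of traced fibroblasts in the labels, if used here, would remove such cells. Extra copies of the segment in the KO cells cannot be told apart from separate changes: the other 43 genes had a median log2 fold change of 0.115 (95% bootstrap interval -0.065 to 0.282), under the bound of 0.15 set in advance to exclude them, but by less than its spread. That test was also set wrongly, as seen only after the value: leaving out the 13 genes that rose pulls the median down, and counting them would push it up, since the window was chosen for them. Over all 56 tested genes the median was 0.297 (95% bootstrap interval 0.073 to 0.511). A haplotype that differs between the mouse lines stays open as well, since no reads are used here. Of the 13 genes 0 were lower, while of the other 43 genes 16 were called higher and 9 lower.

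A hypothesis from the rise of SRF targets was that regions open only in KO carry more CArG boxes, the sites bound by SRF. Among unshared autosomal peaks with a fold of at least 5, 1.06% of 6417 KO summits had a CArG box in the window around the summit (95% Wilson interval 0.837 to 1.34%), against 1.10% of 3461 WT summits (0.801 to 1.5%), so the test showed no excess. Overlapping intervals were the bound set in advance against the hypothesis, but that bound did not allow for spread between libraries, and with 1 library per genotype it stays open. The AP-1 difference was noticed afterwards: the site was found at 13% of KO-only summits (12.2 to 13.8%), 7.77% of WT-only summits (6.93 to 8.71%) and 10.7% of shared summits, the TEAD site at 12.9%, 13% and 12.9%, and the RUNX site at 9.30%, 10.5% and 9.71%. These intervals cover counting error in 1 library per genotype and do not compare the conditions.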
